A study of Homo sapiens with 3 samples.

How the data were processed

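The series holds 3 RNA-seq libraries, 1 each after 0, 3 and 5 days of doxycycline. Per the labels' protocols, total RNA was extracted with RNAiso Plus and libraries were made with a SMARTer mRNA-seq kit. Nothing in the labels says that the counting used strand. Per the file headers, each deposited table gives, for every gene, read counts (unique and total gene reads, exon reads, exon-exon reads and intron reads), a TPM value, an RPKM value not used here, and exon length. The aligner and counter are not given in the sources used here. The genome build in the submitters' processing notes is mm10, a mouse build, whereas all 58243 gene identifiers in the files are human Ensembl identifiers. Of these, 57980 are in GENCODE 29, and 56577 of those (97.6%) have the same start and end on GRCh38, so coordinates are given as GRCh38. The deposited counts were used as they stand. The TPM values are the authors' own and served as an alternative. A further table of the whole series was not used, and its 3 sample columns were left out.

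The day 0, day 3 and day 5 libraries held 21308785, 22068686 and 25754188 total gene reads, of which 89.2%, 88.6% and 87.6% were uniquely placed and 6.01%, 5.59% and 6.68% were intronic. Mitochondrial genes took 0.714%, 0.605% and 0.708% of reads. The 2 chromosome 21 gene models FP236383.1 and FP671120.1, each with 4 ribosomal RNA genes inside it in the RefSeq table, took 1.09%, 1.69% and 1.85%. A count of 3 reads corresponds to 0.139, 0.140 and 0.114 normalised CPM. The labels mention no molecular identifiers, so intervals and floors cover counting error only.

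Total gene reads were normalised with TMM factors (1.01, 0.968 and 1.02) from edgeR 4.0.16 in R 4.3.3. Log2 ratios were formed with a prior count of 0.5, and 95% intervals are exact conditional (Clopper-Pearson) intervals of the ratio. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used. With 1 library per group no model with replicate error could be fitted, so genes were counted by size: a ratio of at least 2-fold with an interval that excludes 1, among genes with a mean of at least 50 reads.

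For each of 33 gene lists and 3 comparisons, the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins. Members were counted at 1.5-fold with an interval excluding 1. Lists with fewer than 5 measured members were given values only. The lists, the comparisons, the rule for named genes and the alternatives said below to be chosen in advance were fixed before the data were examined. The rule always names 8 genes (SYVN1, SRP14, SEL1L, HSPA5, XBP1, ATF4, DDIT3 and HERPUD1). For each of day 3 and day 5 over day 0 it adds the 12 highest and 12 lowest ratios among genes with a mean of at least 200 reads and an interval excluding 1, leaving out pseudogenes, unnamed and antisense transcripts and genes whose direction reverses at the other time. It adds the 6 highest and 6 lowest for day 5 over day 3, and up to 4 members of each list with the largest ratios. Genes with many reads that are not uniquely placed are reported as uncertain, because copies or overlapping genes can exchange them.

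The alternatives chosen in advance were library totals without TMM, DESeq2 1.42.0 size factors, the authors' TPM with 0.5 added, unique reads, exon reads, a prior count of 5, a minimum mean of 10 or 200 reads or none, leaving out mitochondrial genes and the 20 most abundant genes, random lists unmatched or matched on expression and length, an interval excluding 1.5, and protein-coding genes. Alternatives chosen after seeing the data were removal of smooth trends on exon length and transcript GC content (lowess with a span of 0.3, 3 rounds), random lists matched on expression, length and GC content, and genes with at least 90% uniquely placed reads. GC content came from GENCODE 29 transcripts, and 99.2% of compared genes had GC content and length.

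The steps were tested on simulated data. For day 3 over day 0, Poisson counts were drawn for 12487 genes with 200 changed by known folds. All 50 genes changed 4-fold and all 50 changed 3-fold were counted in the right direction, as were 24 of 50 changed 2-fold and 0 of 50 changed 1.5-fold, and 0 of 12287 unchanged genes were counted. Poisson counts hold counting error only, so the last number does not cover variation between cultures. Intervals held the true ratio for 95.2% of genes, and 5 of 100 random lists of unchanged genes lay at or beyond the 2.5 and 97.5 percentiles. In simulated data with length and GC trends added, removal of the trends took a list of 30 short unchanged genes from the 98.9 to the 38.3 percentile and left a list shifted by 0.3 at a median of 0.28.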

Results

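RNA-seq libraries were compared from human cells labelled as LoVo, a colorectal carcinoma line, that carried a doxycycline-inducible (Tet-On) short hairpin RNA. The hairpin targets HRD1, the ubiquitin ligase of endoplasmic reticulum-associated degradation (ERAD), which is encoded by SYVN1. Cells were given 1 µg/ml doxycycline for 0, 3 or 5 days to ask how endoplasmic reticulum (ER) stress from loss of HRD1 alters gene expression. There was 1 library per time, so no difference had a replicate check, no p-value was computed across genes, and each ratio compares libraries rather than conditions. The day 0, day 3 and day 5 libraries held 21308785, 22068686 and 25754188 reads assigned to genes. Square brackets give 95% exact intervals that cover counting error only. A list of genes is said to stand apart where its median lay in the highest 2.5% or lowest 2.5% of 10000 random lists matched on expression, which describes these libraries and is no test of the treatment.

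SYVN1 (ENSG00000162298, GRCh38 chromosome 11, positions 65121780 to 65134533, minus strand) had 1212, 650 and 709 reads at day 0, day 3 and day 5. These were 56.1, 30.4 and 27.0 normalised CPM. The day 3 level was 54.3% of the day 0 level, a log2 ratio of -0.88 [-1.02 to -0.74], and the day 5 level was 48.2% of it, a log2 ratio of -1.05 [-1.19 to -0.92]. Among named protein-coding genes with a mean of at least 200 reads and the same direction at both times, SYVN1 had the lowest log2 ratio at day 5. SEL1L, the partner protein that anchors HRD1, was close to its day 0 level, with log2 ratios of -0.14 [-0.23 to -0.05] at day 3 and -0.02 at day 5. However, the day 3 ratio of SEL1L was 0.01 with trends on exon length and GC content removed and -0.28 with the authors' TPM. The direction of the labels was therefore the direction of the SYVN1 counts. Of 31 enterocyte genes, 0 reached a mean of 50 reads, while keratins of epithelial cells such as KRT8 (465 TPM at day 0) were abundant. The mesenchymal gene VIM was more abundant still (4016 TPM at day 0), and 21 of 27 mesenchymal genes were at 1 TPM or more in each library. The epithelial genes EPCAM and CDH1 stood at 0.724 and 0.0984 TPM at day 0.

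For day 3 over day 0, the question was which transcripts differ early after HRD1 knockdown. Transcripts of ER chaperones and of genes listed as PERK and ATF4 targets were higher in the day 3 library. The activity of PERK itself was not measured. HSPA5, which encodes the chief ER chaperone BiP, was 1.65-fold higher [1.62 to 1.67], with 23137 reads at day 0 and 37668 at day 3. HERPUD1, an ERAD factor induced by ER stress, was 1.60-fold higher [1.51 to 1.69]. XBP1, whose mRNA is spliced by IRE1, was 1.41-fold higher [1.31 to 1.51], and ATF4, the transcription factor translated when PERK is active, was 1.30-fold higher [1.25 to 1.35]. DDIT3, which encodes the stress factor CHOP, was 1.60-fold higher [1.42 to 1.81]. Only 55.1% of DDIT3 reads were uniquely placed, and its log2 ratio was 0.68 from all reads and 0.44 from unique reads.

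Among PERK and ATF4 targets, 29 of 32 measured genes were above their day 0 level. The median log2 ratio was 0.39, at the 100 percentile, and 7 of the 32 were at least 1.5-fold higher while 0 were at least 1.5-fold lower. DDIT4, an inhibitor of mTORC1, had a log2 ratio of 1.05 [0.94 to 1.16] from all reads and 0.99 from unique reads. CTH, which makes cysteine from cystathionine, had 0.89 [0.58 to 1.20], and SESN2, a stress-induced sestrin, had 0.77 [0.54 to 1.01]. Asparagine synthetase (ASNS) had 0.86, but only 4.10% of its reads were uniquely placed, and unique reads gave 0.48 [-0.04 to 1.01]. ER chaperones and ATF6 targets had a median of 0.33 at the 100 percentile, with 19 of 21 above the day 0 level and 4 at least 1.5-fold higher. The members with the highest ratios were HSPA5, HERPUD1, SDF2L1 (0.61) and HSP90B1 (0.59). XBP1 and IRE1 targets had a smaller median of 0.14 at the 99.1 percentile, and only DNAJB9, a BiP co-chaperone, with 0.61 [0.29 to 0.93], was at least 1.5-fold higher among 20. The cytosolic aminoacyl tRNA synthetases, many of them ATF4 targets, were all above the day 0 level (19 of 19, median 0.18, percentile 99.4), with GARS at 0.39 and SARS at 0.38, but the list lay at the 91.98 percentile with the authors' TPM. Random lists matched to it on expression had a median of 0.065.

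**Figure D1:**
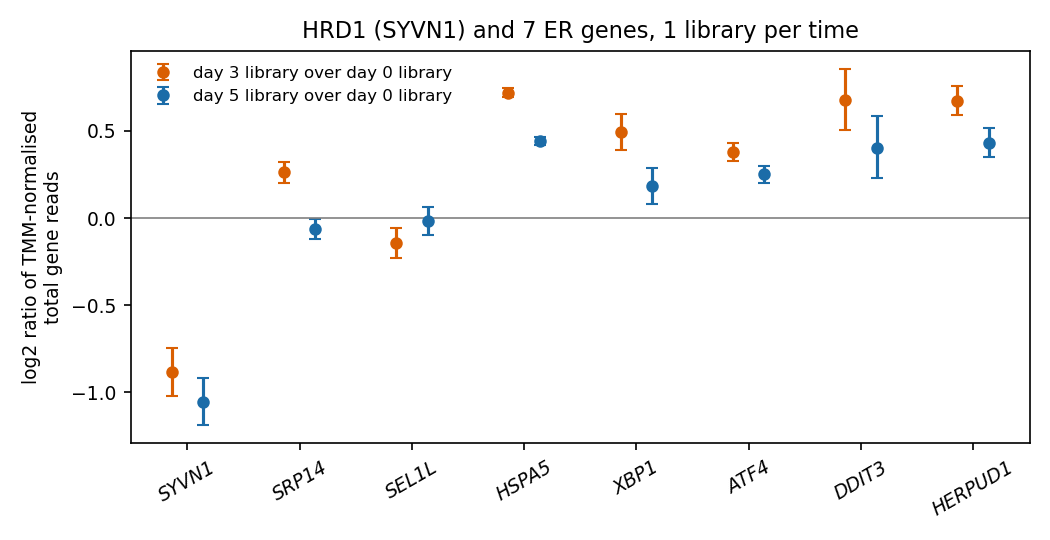
Log2 ratio of TMM-normalised total gene reads over the day 0 library for SYVN1 and 7 ER-related genes, with day 3 in orange and day 5 in blue. Bars are 95% exact intervals that cover counting error only, and SYVN1 lies at -0.88 and -1.05 while HSPA5 lies at 0.72 and 0.44.

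Machinery that delivers proteins into the ER was measured as a separate group, since the series concerns translocation into the ER. SRP14 (ENSG00000140319, GRCh38 chromosome 15, positions 40035739 to 40039188, minus strand), a subunit of the signal recognition particle, was 1.20-fold higher at day 3 [1.15 to 1.25] and 0.957 of its day 0 level at day 5 [0.919 to 0.998]. Its reads numbered 4245, 5035 and 4937. The 8 genes of the particle and its receptor were all above day 0 at day 3 with a median of 0.16, at the 97.3 percentile, which did not stand apart. At day 5 the median was 0.08 at the 93.5 percentile. None of the 8 was 1.5-fold different, and the highest at day 3 were SRPRB (0.35) and SRP54 (0.29). The translocon, TRAP, signal peptidase and oligosaccharyltransferase genes stood apart at both times, with medians of 0.17 at day 3 (percentile 99.9) and 0.14 at day 5 (percentile 100), although with the authors' TPM they lay at 96.3 at day 3. Their members differed little between libraries. SEC61G, a small subunit of the SEC61 channel, had 0.59 [0.46 to 0.72] at day 5, and it was the only one of 29 at least 1.5-fold higher. With the length and GC trends removed it had 0.39, and 0 of the 29 were at least 1.5-fold higher. The list of 29 ERAD genes, which holds neither SYVN1 nor HERPUD1, did not stand apart at day 3 (median 0.07, percentile 80.8) or at day 5 (median -0.00, percentile 56.8), and none of its members was 1.5-fold different.

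Few genes differed by 2-fold. Among 12593 genes with a mean of at least 50 reads, 25 were at least 2-fold higher and 57 at least 2-fold lower at day 3, and 96.1% were within 1.5-fold. Where only genes with at least 90% uniquely placed reads were counted, these numbers were 3 and 17 of 9100. Simulated unchanged libraries with an assumed coefficient of variation of 0.1 between them gave 2 higher and 1.7 lower genes of 12593 at day 3. With 0.2, which gave more spread than the data, they gave 134 and 128. AGR2, a protein disulfide isomerase of the ER in mucus-secreting cells, was 2.12-fold higher [1.88 to 2.41], with 372 reads at day 0 and 782 at day 3. TXNIP, a thioredoxin inhibitor, had a log2 ratio of 0.84 [0.55 to 1.15]. The other high ratios belonged largely to genes with few uniquely placed reads. SMIM11B (4.28), EIF3CL (2.19) and HFM1 (1.55) had 1.37%, 1.63% and 0.953% uniquely placed reads, and their ratios are uncertain, as are those of MDP1 (0.89), PYURF (0.84) and C7orf25 (0.82) at 35.2%, 4.83% and 26.3%. Among named protein-coding genes with a mean of at least 200 reads and the same direction at both times, ALPP, placental alkaline phosphatase, was lowest at 0.339 of its day 0 level [0.276 to 0.412]. ZNF280C (-0.98), RIPOR3 (-0.92), ONECUT2 (-0.91), SHISA2 (-0.80), ROR1 (-0.74), KIF14 (-0.74) and GLIS3 (-0.71) followed. ONECUT2, KIF14 and GLIS3 have large exon lengths (16234, 7277 and 11558 bases). Across the alternatives their log2 ratios ranged from -1.06 to -0.68, -0.89 to -0.63 and -0.78 to -0.56. ANKRD30A had -0.80 from all reads but -0.49 from unique reads. UCA1_1 (-0.83) and TVP23C-CDRT4 (-0.71) had under 50% uniquely placed reads, at 48.9% and 3.32%.

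Of 29 lists tested, 11 stood apart above and 1 below at day 3, and 9 and 2 at day 5, against 1.45 per comparison if genes varied independently. Members of a list need not do so and some lists share genes, so 1.45 is no measure of variation between cultures. Fewer lists also stood apart both with length and GC trends removed and with random lists matched on expression, length and GC content. These were 10 above and 1 below at day 3, and 6 and 1 at day 5. At day 3, cytosolic ribosomal protein genes were all above their day 0 level (78 of 78, median 0.30, percentile 100), as were 41 of 42 nuclear oxidative phosphorylation genes (median 0.23, percentile 100), 41 of 45 mitochondrial ribosomal protein genes (median 0.18, percentile 100) and 29 of 31 proteasome subunits (median 0.19, percentile 99.98). None of these 4 lists held a gene with a 1.5-fold difference, and the proteasome list lay at the 95.9 percentile with the authors' TPM. Expression-matched random lists also had medians above 0, at 0.10, 0.03, 0.01 and 0.06 in the order given. Glycolysis and hypoxia genes had a median of 0.30 (26 of 27 above day 0, percentile 100). Among them, PDK1, which inhibits pyruvate dehydrogenase, had 0.62 [0.41 to 0.84] and BNIP3, a mitophagy receptor, had 0.62 [0.52 to 0.71]. The p53 list had a median of 0.18 (percentile 99.95), led by SESN2, which is also on the ATF4 list. Mitochondrially encoded mRNAs were lower, with a median of -0.17 at the 0.0400 percentile, and MT-ND4L had -0.44 [-0.49 to -0.38].

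The libraries also differed by the exon length of genes and the GC content of their transcripts. Across 12487 genes, which are not independent replicates, the log2 ratio at day 3 had a Spearman correlation of -0.38 with exon length, and its median was 0.16 in the shortest eighth of genes and -0.15 in the longest. At day 5 the correlation with length was -0.10 and that with GC content was -0.43, with medians of 0.14 in the eighth of lowest GC and -0.13 in that of highest GC. For day 5 over day 3 the correlation with GC content was -0.54, with medians of 0.20 and -0.18 in the same eighths. Smooth trends on both were therefore removed as an alternative chosen after the data were seen. The PERK and ATF4 list then had medians of 0.32 at day 3 and 0.19 at day 5, and the ER chaperones 0.28 and 0.16, all 4 at the 100 percentile. Ribosomal protein genes had 0.24 and 0.10. The p53 list at day 3 no longer stood apart, at the 96.7 percentile, whereas S phase genes at day 3 went from the 46.6 to the 0.270 percentile. SRP14 had 0.14 at day 3 and -0.14 at day 5, and ATF4 had 0.26 at day 3 rather than 0.38.

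**Figure D2:**
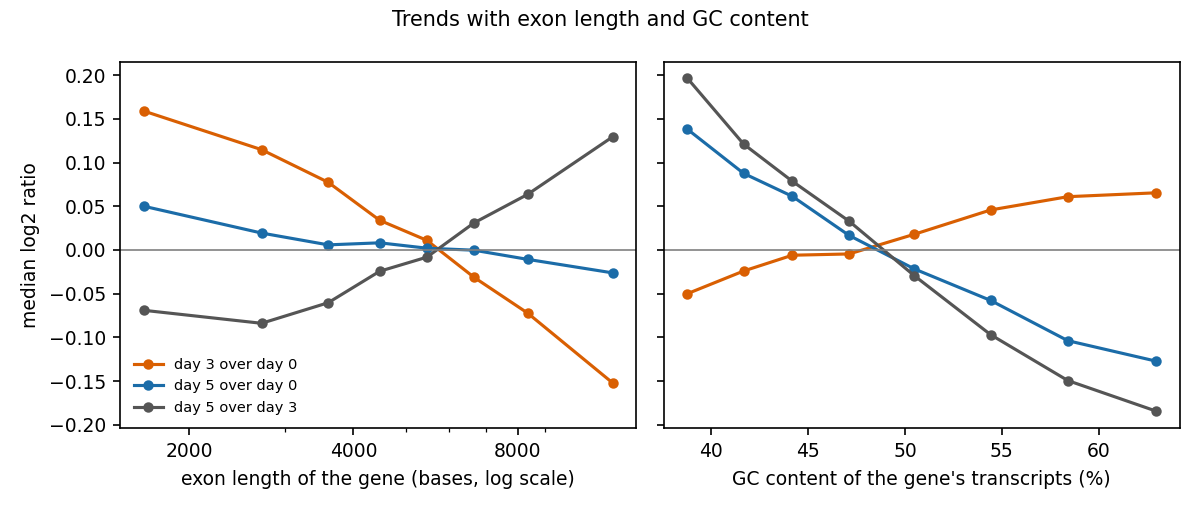
Median log2 ratio of genes in 8 equal groups by exon length in bases (left, log scale) and by GC content of the transcripts in percent (right), for the 3 comparisons of libraries. The day 3 over day 0 line falls from 0.16 to -0.15 with length, and the day 5 over day 0 line falls from 0.14 to -0.13 with GC content.

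For day 5 over day 0, the same ER genes were higher, by less. HSPA5 was 1.36-fold higher [1.33 to 1.38], HERPUD1 1.35-fold [1.27 to 1.43], ATF4 1.19-fold [1.15 to 1.23] and XBP1 1.14-fold [1.06 to 1.22]. DDIT3 had a log2 ratio of 0.40 [0.23 to 0.58] from all reads and 0.09 [-0.14 to 0.33] from unique reads, so its difference was not detectable with the latter. PERK and ATF4 targets had a median of 0.20 at the 100 percentile (28 of 32 above day 0, 1 at least 1.5-fold higher), with CTH at 0.68 [0.38 to 0.99], SESN2 at 0.57, DDIT4 at 0.57 and GDF15, a stress-induced cytokine, at 0.54 [0.32 to 0.77]. ER chaperones had a median of 0.13 at the 99.9 percentile, with 20 of 21 above day 0 and MANF, a secreted ER stress protein, at 0.56 [0.48 to 0.65]. XBP1 and IRE1 targets (median 0.09, percentile 97.4) fell just short of standing apart. The tRNA synthetases had a median of 0.06 at the 98.2 percentile, but at the 97.4 percentile after the trends were removed and at 91.1 with the authors' TPM. The day 5 library also held reads of liver, intestine and blood genes that were near 0 in the others, such as ALB with 0, 0 and 114 reads at day 0, day 3 and day 5.

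At day 5, 38 genes were at least 2-fold higher and 28 at least 2-fold lower, or 7 and 10 among genes with uniquely placed reads. AGR2 was again high, at 2.07-fold [1.83 to 2.34]. Across the alternatives its log2 ratio ranged from 0.98 to 1.09 at day 3 and from 0.91 to 1.06 at day 5, so the 2-fold call did not hold under each. RPS29 (1.09), ATP5I (1.04) and TMA7 (0.78), which encode a ribosomal protein, an ATP synthase subunit and a translation-associated protein, were higher, as was the metallothionein MT1X (0.78). The log2 ratio of RPS29, with 71.4% uniquely placed reads, ranged from 0.79 to 1.10 across the alternatives, and that of ATP5I from 0.98 to 1.06. Their 2-fold calls therefore did not hold under each. FP236383.1 (0.77), a gene model on chromosome 21 with ribosomal RNA genes inside it, and NME1-NME2 (1.35), XAGE1A (1.27), NPIPB12 (0.93), HFM1 (3.58), SMIM11B (4.56) and EIF3CL (2.28) had at most 10.8% uniquely placed reads and are uncertain. With the authors' TPM, HFM1 had 0.09 at day 3 and 0.55 at day 5. CHCHD10 (-1.30), a mitochondrial intermembrane protein, and DNLZ (-0.93) were also lower, but had ratios slightly above 0 at day 3. Among named protein-coding genes with a mean of at least 200 reads and the same direction at both times, the lowest after SYVN1 were ALPP (-1.05), SUSD2 (-0.90), EBPL (-0.87), UCP2 (-0.83), SMAD6 (-0.82), BCORL1 (-0.79), MRC2 (-0.76), HR (-0.76) and INHBA (-0.73). Transcripts of SUSD2, MRC2 and HR are rich in GC (63.5%, 63.2% and 64.8%). Across the alternatives their log2 ratios ranged from -0.91 to -0.76, -0.80 to -0.60 and -0.77 to -0.57. MSH5 (-0.84) and PPT2-EGFL8 (-0.74) had 13.5% and 23.5% uniquely placed reads. Unique reads gave -0.94 for MSH5 and -0.03 [-0.54 to 0.49] for PPT2-EGFL8, whose difference was not detectable with them.

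S phase genes were lower at day 5, with a median of -0.15 at the 0.00 percentile and 26 of 34 at or below the day 0 level, among them SLBP at -0.44 [-0.51 to -0.37] and thymidine kinase TK1 at -0.33 [-0.39 to -0.28]. None reached 1.5-fold. G2 and M phase genes did not stand apart (35 genes, median -0.00, percentile 67.4), but after the trends were removed they lay at the 0.140 percentile. The mesenchymal list was lower (19 genes, median -0.14, percentile 0.480), led by THBS1 at -0.51 [-0.54 to -0.47], but lay at the 5.03 percentile after the trends were removed and at 5.15 with no read minimum. Glycolysis and hypoxia genes were again higher (median 0.17, percentile 100), with PDK1 at 0.73 [0.53 to 0.94] and BNIP3 at 0.65 [0.56 to 0.74]. Cytosolic ribosomal protein genes (median 0.12, percentile 100, 7 of 78 at least 1.5-fold higher), oxidative phosphorylation genes (0.11, percentile 99.99) and mitochondrial ribosomal protein genes (0.09, percentile 99.8) stood apart, the last no longer after the trends were removed (percentile 93.1) and oxidative phosphorylation no longer with unique reads (percentile 93.68). Proteasome subunits (0.03, percentile 94.045) and p53 targets (0.09, percentile 94.5) did not, although p53 targets lay at the 99.6 percentile after the trends were removed. Cholesterol synthesis genes had a median of 0.11 at the 99.7 percentile, but 97.2 after the trends were removed and 96.6 with unique reads, with MSMO1 at 0.43 [0.34 to 0.52].

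**Figure D3:**
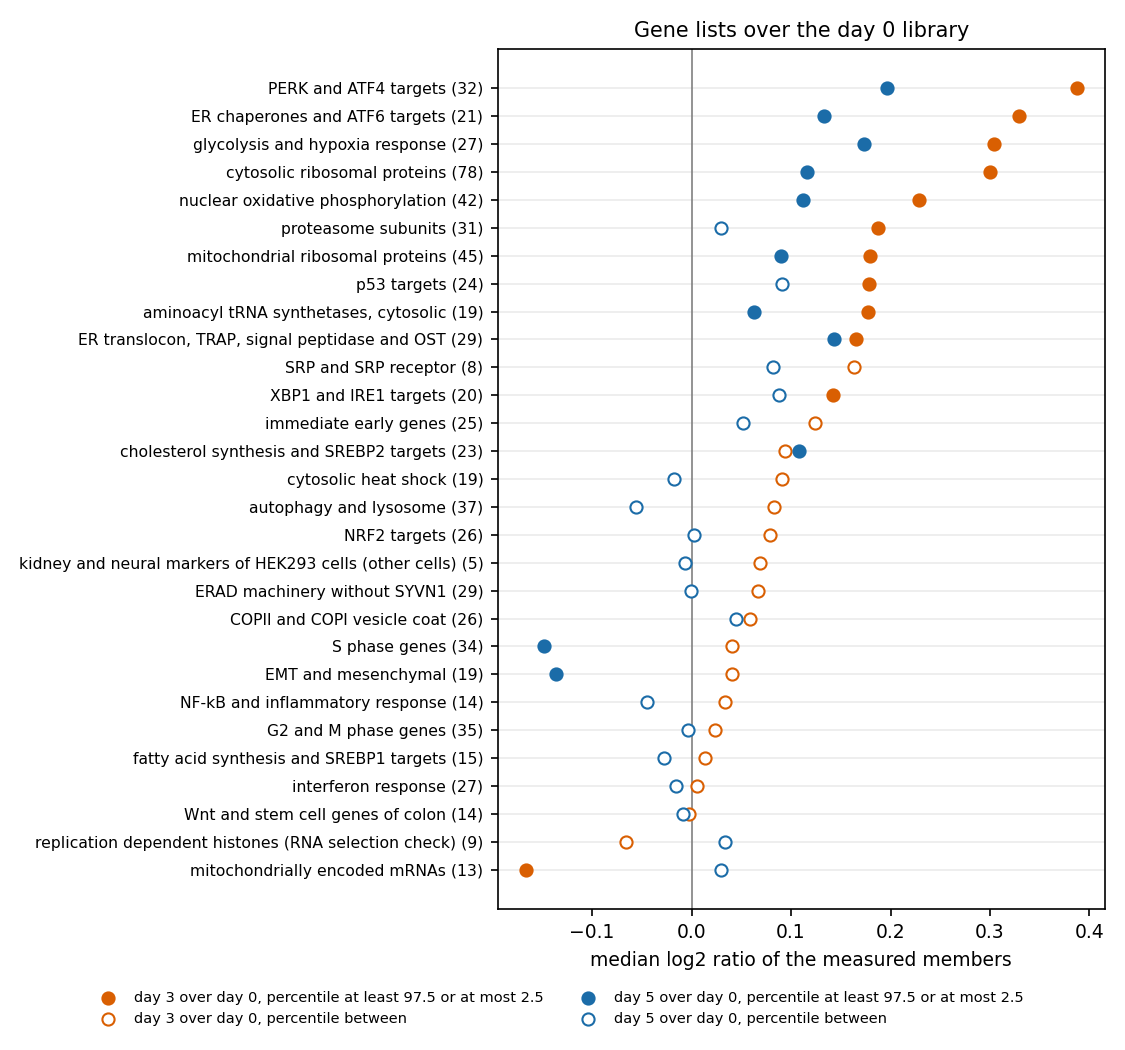
Median log2 ratio over the day 0 library of the measured members of 29 gene lists, with the number measured in parentheses. Filled points lie in the highest or lowest 2.5% of expression-matched random lists, and the PERK and ATF4 list has the highest medians, 0.39 at day 3 and 0.20 at day 5.

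Day 5 was then compared with day 3. The PERK and ATF4 targets were lower at day 5 (median -0.20, percentile 0.0100, 28 of 32 below day 3), with DDIT4 at -0.48 [-0.57 to -0.39] and PHGDH, which starts serine synthesis, at -0.48 [-0.57 to -0.40], while the cystine transporter SLC7A11, with 32.5% uniquely placed reads, was at 0.52 [0.46 to 0.59]. ER chaperones had a median of -0.16 at the 3.98 percentile, and at the 1.14 percentile after the trends were removed, with SDF2L1 and CRELD2 both at -0.49. SYVN1 had a log2 ratio of -0.17 [-0.33 to -0.02]. SRP14 had -0.33 [-0.38 to -0.27], and the list of the particle and its receptor lay at the 29.5 percentile, or 0.570 after the trends were removed. Proteasome subunits were lower (median -0.16 against -0.07 for matched random lists, percentile 2.40). Cytosolic ribosomal proteins were lower as well (median -0.18 against -0.12, percentile 1.37), but neither call held throughout. With random lists matched on length they lay at the 16.3 and 7.38 percentiles, and with the authors' TPM at 18.95 and 53.4, and ribosomal proteins lay at 10.7 after the trends were removed. Mitochondrially encoded mRNAs were higher (median 0.14, percentile 99.98), led by MT-ATP8 at 1.37 [1.25 to 1.48] and MT-ND3 at 0.81, but lay at the 94.6 percentile of unmatched random lists. In all, 60 genes were at least 2-fold higher and 25 lower, or 13 and 7 among genes with uniquely placed reads. CHCHD10 was 0.377 of its day 3 level [0.326 to 0.435], and HES4, a Notch target, was 0.529 of it [0.440 to 0.633]. Their transcripts hold 66.4% and 74.2% GC, and this comparison had the strongest trend with GC content. Across the alternatives their log2 ratios ranged from -1.46 to -1.22 and from -0.93 to -0.74. EBPL had -0.87, and DNLZ had -0.99 from all reads and -1.53 from unique reads. The high ratios of C7orf55-LUC7L2 (1.88), HIST2H2AA4 (1.48) and HFM1 (2.03) and the low ratios of XAGE1B (-2.79) and HSPA1A (-0.89) came from genes with at most 10.8% uniquely placed reads.

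The ratios at day 3 and day 5 share the day 0 library, which could not be split. Across 12593 genes they had a Pearson correlation of 0.44, a Spearman correlation of 0.39 and a covariance of 0.0383. Unchanged libraries simulated with the same shared day 0 library gave a correlation of 0.52 with Poisson counting error, 0.50 with a coefficient of variation of 0.1 between libraries and 0.50 with 0.2, so the observed correlation was no higher than that from the shared library. The simulated covariances were 0.00706, 0.0280 and 0.0922, so the observed one exceeded the first 2 by 0.0313 and 0.0103 and was below the third. The third had more spread than the data, so it is no equal reference. Its log2 ratios had standard deviations of 0.430 and 0.429 at day 3 and day 5, against 0.303 and 0.287 observed. At a variation of 0.1 they were 0.237 and 0.234. At both times 14 genes were at least 2-fold higher and 3 at least 2-fold lower. Independent lists would share 0.0754 and 0.127 genes. Simulated libraries shared 0.3 and 0 genes at a variation of 0.1, and 29.6 and 9.95 at 0.2. Part of the excess may come from the shared day 0 library. Of the 14 and 3 genes, 2 (AGR2 and SPINK5) and 1 (ALPP) had at least 90% uniquely placed reads.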

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

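All tests in this part were chosen after the results were seen, except that of read depth for the colon genes. Among the 57 genes always named or ranked highest or lowest, 5 had day 3 and day 5 libraries on opposite sides of day 0, with both counting intervals excluding 1. The same held for 87 of 741 measured list members, 76 of them higher at day 3 and lower at day 5, such as TK1 (0.14 and -0.33) and the ERAD gene VCP (0.10 and -0.21). The share over all genes was not counted. Random lists matched to ribosomal proteins on expression went the same way, with medians of 0.10 at day 3 and -0.02 at day 5. None of the differences in single genes was tested, since each time had 1 library. SRP14 was higher at day 3 and slightly lower at day 5, a log2 difference of -0.33 between the times, and its day 5 interval included no difference when unique reads were used (-0.05 [-0.11 to 0.01]). MT-ATP8 had log2 ratios of -0.21 at day 3 and 1.16 at day 5, a difference of 1.37. HSPA1A had 0.28 and -0.60, a difference of -0.89, with 10.8% uniquely placed reads. C7orf55-LUC7L2 had -1.19 and 0.68, a difference of 1.88, with 0 uniquely placed reads, and HIST2H2AA4 had -0.71 and 0.78, a difference of 1.48, with 2.68% uniquely placed reads.

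The PERK and ATF4 targets and the ER chaperones stood apart in both doxycycline libraries. Trends on exon length and GC content are argued against as the whole cause. The lowest of the 4 percentiles (2 lists at 2 times) was 100 after both trends were removed. For the lists of cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation and proteasome at day 3, the lowest percentile after removal was 98.8. Part of their shifts went with the trends, as the median of mitochondrial ribosomal proteins went from 0.18 to 0.10 and that of cytosolic ones from 0.30 to 0.24. Exon length was given per gene (8344 bases for RPS29), not per mRNA. A trend on mRNA length could therefore not be removed and stays open. Doxycycline acting apart from the knockdown stays open, since 0 of the libraries analysed here had doxycycline without the hairpin against HRD1. A chance difference between single cultures stays open as well.

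Most enterocyte genes were near 0 in the 3 libraries (CDX2 had 0 reads in each, CEACAM5 had 0, 1 and 2), and of genes chosen after their values were seen, EPCAM and CDH1 stood at 0.724 and 0.0984 TPM at day 0, whereas AXL stood at 581 and the epithelial keratins KRT7, KRT8, KRT18 and KRT19 at 935, 465, 728 and 137. AGR2 of the secretory list stood at 25.2 TPM. Loss of these genes after doxycycline is argued against, because 2 of the 31 enterocyte genes (CA2 and TFF3) were at 1 TPM or more at day 0, before any doxycycline. Too few reads to see these genes is argued against, because 3 reads were worth 1 TPM or more for 2 of the 31, with a median of 0.229 TPM. Cells other than the labelled line would leave these genes low throughout, and 2 of the 31 were at 1 TPM or more in every library, but a subline of the labelled cells without these genes would do the same and was not tested.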

How the results depend on the processing

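No paired analysis was possible because each time had 1 library, and for the same reason no library could be left out. Removal of length and GC trends, matching on expression, length and GC content, and the restriction to uniquely placed genes were chosen after the data were seen. SYVN1 ranged from -0.99 to -0.88 at day 3 and from -1.08 to -0.95 at day 5. The PERK and ATF4 targets and the ER chaperones stood apart at both times under each alternative. The correlation of day 3 and day 5 ratios ranged from 0.40 to 0.50. Of the counts, overlaps and correlations 74 kept within 1.5 times and 52 did not. Of the list percentiles 1133 kept their call, 47 became stronger, 23 weaker and 6 reversed. Of the log2 ratios of named genes 741 kept their size, 48 moved and 2 reversed. Unless said below, the cause was not tested.

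Read minimums changed the counts of 2-fold genes by construction. With a mean of 10 reads, 174, 259 and 344 genes were higher and 307, 205 and 169 lower (day 3 over day 0, day 5 over day 0, day 5 over day 3, an order kept below), with 81 higher and 62 lower at both times, and the signal recognition particle list at day 3, at 97.3 otherwise, lay at 97.6. With a mean of 200 these were 6, 10 and 8 higher, 6, 7 and 5 lower, and 5 and 1 at both times. With no minimum they were 326, 480 and 605 higher, 511, 417 and 340 lower, and 110 and 138 at both times.

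Unique reads gave 6, 12 and 20 higher, 26 lower at day 3, 18 lower at day 5, and 4 and 1 at both times, with the signal recognition particle list at 99.8 at day 3. Exon reads gave 15 higher at day 3 and 34 for day 5 over day 3, 29, 17 and 15 lower, and that list at 99.1. Uniquely placed genes alone gave 3, 7 and 13 higher, 17, 10 and 7 lower, and 2 and 1 at both times. Protein-coding genes alone gave 32 higher for day 5 over day 3 and 26, 15 and 15 lower.

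The authors' TPM gave 59 higher at day 5, 92 higher for day 5 over day 3 and 8 lower at both times. FP236383.1 at day 5 had -0.11, the opposite direction, the translocon list at day 3 lay at 96.3 and cytosolic ribosomal proteins for day 5 over day 3 at 53.4, on the other side of the middle.

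The signal recognition particle list at day 3 was lower with the authors' TPM (92.4), with the trends removed (93.1), with lists matched on expression, length and GC content (94.2) and on expression and length (87.0).

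Removal of the trends gave 6 lower at both times. For day 5 over day 3 it also set apart tRNA synthetases (10.6 to 0.1), the signal recognition particle list (29.5 to 0.57), glycolysis genes (13.4 to 2) and oxidative phosphorylation genes (2.63 to 1.43). Histones at day 3 lay at 2.12 with lists matched on expression, length and GC content and at 1.23 with lists matched on expression and length. SEL1L at day 3 had 0.00628, opposite in sign, G2 and M phase genes at day 5 lay at 0.14, Wnt genes for day 5 over day 3 at 97.84 and mitochondrially encoded mRNAs at day 5 at 0. With lists matched on expression, length and GC content, G2 and M phase genes at day 5 lay at 0.76 and mitochondrially encoded mRNAs at 1.365. Across all alternatives the mitochondrially encoded mRNAs at day 5 ranged from 0 to 98.755, so they stood apart in either direction. XBP1 and IRE1 targets at day 5 lay at 97.6 with a prior count of 5, 97.7 without abundant and mitochondrial genes, 97.6 with lists matched on expression and length, 98.9 with the trends removed and 98.0 with lists matched on all 3.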

Other observations

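Several lists fixed in advance did not stand apart, or did so at a single time. Immediate early genes had medians of 0.12 at day 3 (25 genes, percentile 96.8) and 0.05 at day 5 (percentile 93.1, and 100 after the trends were removed), with ATF3, a stress-induced transcription factor, at 0.58 and 0.40, and NR4A2 at 0.87 [0.37 to 1.42] at day 5. In the NF-kB and inflammatory list (14 genes, percentiles 69.8 and 21.8), the chemokine gene CXCL8 had 0.80 [0.40 to 1.21] and 0.99 [0.62 to 1.39], and BIRC3 had 0.66 at day 5. The colon Wnt and stem cell list lay at the 44.0 and 42.9 percentiles (14 genes), with MYC at 0.32 and 0.37. Fatty acid synthesis genes lay at 27.3 and 38.3 (15 genes), with FASN at -0.18 and -0.40. The interferon list lay at 54.7 and 26.5 (27 genes), NRF2 targets at 80.2 and 59.2 (26 genes), autophagy and lysosome genes at 93.9 and 5.39 (37 genes), COPII and COPI coat genes at 63.2 and 96.1 (26 genes) and cytosolic heat shock genes at 64.9 and 48.7 (19 genes), among which HSPE1 had 0.65 at day 5. Cholesterol genes at day 3 lay at 86.8. Replication dependent histones lay at 14.3 and 61.1 (9 genes), but at day 3 they stood apart below once length was taken into account, at 1.23 after the trends were removed. Autophagy and lysosome genes at day 3 likewise stood apart with random lists matched on length (98.8), though not after the trends were removed (93.3).

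Of the secretory lineage of the colon, 3 of 28 genes were measured. AGR2 was higher while the mucins MUC5AC (-0.47 and -0.56) and MUC5B (-0.31 and -0.54) were lower, although the day 3 interval of MUC5B included no difference. With the length and GC trends removed, the median of the 3 genes went from -0.31 to -0.09 at day 3 and from -0.54 to -0.29 at day 5. Of markers of other cells, 3 of 20 fibroblast and endothelial genes were measured, with PDGFRB at -0.79 and -1.17, PECAM1 at -1.11 and -0.77, and COL1A1 at 0.19 and -0.00. The difference of PECAM1 was smaller by the authors' TPM, at 1.07, 0.747 and 0.851 at day 0, day 3 and day 5. The kidney and neural markers of HEK293 cells lay at the 68.8 and 45.0 percentiles (5 of 16 genes). Of 23 blood and immune genes, 2 were measured, LCP1 at 0.34 and 0.29 and CD68, with 24.8% uniquely placed reads, at 0.27 and -0.08.

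Some of the highest ratios were mirrored in a near-identical copy. SMIM11A had 222, 26 and 15 reads at day 0, day 3 and day 5 while SMIM11B had 13, 258 and 386, so that the sum had log2 ratios of 0.29 and 0.49. XAGE1A had 428, 480 and 1252 reads while XAGE1B had 463, 515 and 91, and the sum had 0.18 and 0.31. EIF3CL was higher at both times while the sum with EIF3C had 0.21 and -0.05.

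Traces of liver, intestine and blood transcripts appeared in the day 5 library, and the tests on them were chosen after the first of these genes had been seen. ALB had 0, 0 and 114 reads at day 0, day 3 and day 5, FGB had 0, 0 and 122, APOA1 had 0, 2 and 78, FABP2 had 0, 0 and 32, and HBB had 1, 3 and 28. Some such genes already had reads at day 3, such as CD74 with 0, 17 and 26 and APOB with 0, 12 and 18. Protein-coding genes with at most 2 reads at day 0 and at least 15 at day 5 numbered 56, against 13 for day 3 and 9 in the opposite direction from day 5 to day 0. A list of 36 further hepatocyte genes was then written down before its reads were looked at. Of the 26 with at most 2 reads at day 0, 12 had 3 or more at day 5 and 0 had so at day 3. This was short of the 13 of 26 set beforehand for RNA or reads from liver mixed into the library, so this explanation stays open. The test covered hepatocyte genes only and cannot tell it apart from expression by the cells. Blood and immune genes, which it did not cover, were at 1 TPM or more for 3, 4 and 12 of 23 at day 0, day 3 and day 5. The greater depth of day 5 is argued against as the whole cause, since summed reads of all 36 genes were 293, 237 and 660, a depth-scaled ratio of 1.85 over day 0 with a lower bound of 1.61 from counting error alone. Single genes weigh on this ratio, as CPS1 held 212, 189 and 268 of the reads and TF 4, 1 and 126.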
